A study of Mus musculus with 6 samples.

How the data were processed

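Gene expression was measured in presomitic mesoderm (PSM), the tissue from which somites form, of mouse embryos at embryonic day 8.75. Each of the 6 arrays held RNA from 1 pool of 3 dissected anterior PSMs, and each genotype had 3 pools that the labels call biological replicates. RNA was extracted with a PicoPure kit, labelled with a 3' IVT Express kit and hybridized to Affymetrix whole-genome mouse expression arrays. Control embryos were R26R^AC/AC, and mutant embryos were R26R^AC/AC;T-Cre.

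The authors deposited 1 linear intensity value per probe set and array, already summarised and scaled, and the submitters' processing notes name Affymetrix Expression Console and MAS5. Their versions, the scaling target and the rule that left 19606 probe sets in the table were not stated in the sources used here. Detection calls and scanner files were not used here. The values were positive, had about the same median on each array and were not logged, so they were read as scaled signal, and the authors' scaling was kept. Of the 19606 probe sets, 55 were array controls. Of the other 19551, 17842 were listed in the annotation table supplied for the platform, which gave 17348 of them exactly 1 gene symbol and 494 several symbols, and 1709 were not named. Of the probe sets with 1 symbol, 17316 carried an Entrez identifier found in the RefSeq gene table of GRCm38.p6, and 0 symbols had to be replaced. The authors' files name no genome build, so no coordinates are given.

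The lists, tests, naming rule and most alternatives were fixed before the data were examined. Signals were analysed as log2 of the signal plus 1. Probe sets whose mean of the 6 log2 values lay below the 40th percentile of these means, which corresponds to a geometric mean signal of 349, were left out, which left 11731 probe sets. At the gene level, each gene was represented by the tested probe set with 1 symbol and the highest mean log2 signal, which gave 7245 genes. Mutant pools were compared with control pools by limma (version 3.58.1, R 4.3.3), with a linear model on genotype and empirical Bayes moderation with an intensity trend, two-sided. Benjamini-Hochberg adjusted p under 0.05 was called a change, and log2 differences are mutant minus control, each with its standard error (SE) and 3 pools per genotype. Median SE was 0.14 for genes, and the smallest difference that was called among genes was 0.44 in absolute log2 units. The number of arrays limits the precision.

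There were 28 gene lists: Notch, Wnt, FGF, retinoic acid, Hedgehog, and BMP and TGF-beta pathways, posterior PSM and tail bud, somite segmentation and polarity, differentiating somite, CREB targets, CREB family with cofactors and cAMP signalling, Hox genes, cell cycle, p53 response and apoptosis, glycolysis and hypoxia, unfolded protein and amino acid response, sterol synthesis, adhesion and matrix, oxidative phosphorylation and ribosome, immediate early and heat shock genes as a sign of handling, markers of neural tube, notochord and floor plate, gut endoderm, surface ectoderm, blood, endothelium, and lateral and intermediate mesoderm, and sex-linked genes. Each list with at least 5 tested genes was compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, and p was adjusted over the 26 such lists. Camera with an estimated correlation, and fry, were alternatives. A count adjusted over the list alone is given beside the count over all genes. Named genes were the 10 called genes per direction with the largest change and no overlap between genotypes, up to 4 members of each list with the smallest p, and T, Creb1, Crem, Atf1 and Gt(ROSA)26Sor where measured. Rik, clone, Gm and LOC symbols were counted but not named. T and Atf1 had no probe set in the table used.

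Array quality was checked by median signal, correlation, principal components and the 3' to 5' signal ratios of the spiked dap, thr, phe and lys control transcripts, which enter before labelling. The same ratios of the array's control probe sets for Actb and Gapdh were also taken. The dap ratio parted the arrays into 3 above 15 (control 1, mutant 1 and mutant 2, called high-ratio arrays here) and 3 below it. The spike-in ratio block, which adds this split to the model, and the differences within each set, which rest on 1 pool of 1 genotype and 2 of the other, were chosen after seeing the data. Replicate numbers were checked for pairing by correlating residuals between genotypes. The residual r of equal numbers was 0.20, −0.45 and 0.37, and 2 of the 6 arrays correlated best with the array of their own number, so the arrays were not treated as pairs.

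The other alternatives were quantile normalization, median centring, offsets of 16 and 64, no filter, a filter at the 60th percentile, no intensity trend, array quality weights, replicate number as a covariate, adjusted p under 0.1, the mean of a gene's probe sets, no cross-hybridising probe sets (_x_at and _s_at), an equal-variance test per gene, and leaving out each array in turn. The model was tested on simulated data with 11731 probe sets and 3 arrays per genotype. It called 56.7% of probe sets changed 1.5-fold, 92.5% of those changed 2-fold and 90.9% of those changed 4-fold, all with the right sign, and 7.51% of its calls were wrong. Up to 1 probe set was called in 5 simulations with no change, and 0 of 50 unshifted lists were called, with probe sets simulated independently of each other. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.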

Results

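The data were 6 genome-wide expression arrays of anterior PSM at embryonic day 8.75, from 3 control pools (R26R^AC/AC) and 3 mutant pools (R26R^AC/AC;T-Cre), each pool of 3 PSMs. T-Cre is a Cre recombinase driven by the promoter of T (Brachyury), which is active in the primitive streak and its mesoderm. AC is understood, from knowledge of the study rather than from the labels, as A-CREB, a dominant-negative inhibitor of the CREB family of transcription factors that Cre switches on from the ROSA26 locus. Median signal per array lay between 491 and 535, and the 5th percentile between 59.6 and 72.5. Both were taken over the 19551 probe sets in the table that are not array controls, so they may differ from those of the whole array. Pearson's r across probe sets, which are not independent replicates, was 0.963 to 0.993 between arrays. The first principal component held 44.8% of the variance and the second 30.8%. The second one parted the genotypes, with −27.1, −1.32 and −1.37 in control 1, 2 and 3 and 11.9, 5.02 and 12.9 in mutant 1, 2 and 3. The first one parted control 1, mutant 1 and mutant 2 from the other 3 arrays. These 3 arrays had dap spike-in ratios of 22.9, 23.8 and 19.6, against 12.2, 11.1 and 10.2 in control 2, control 3 and mutant 3. Control 1 also stood apart in the bioB hybridization control, whose 5' probe set read 531 in it and 62.4 to 108 in the other arrays.

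**Figure D1:**
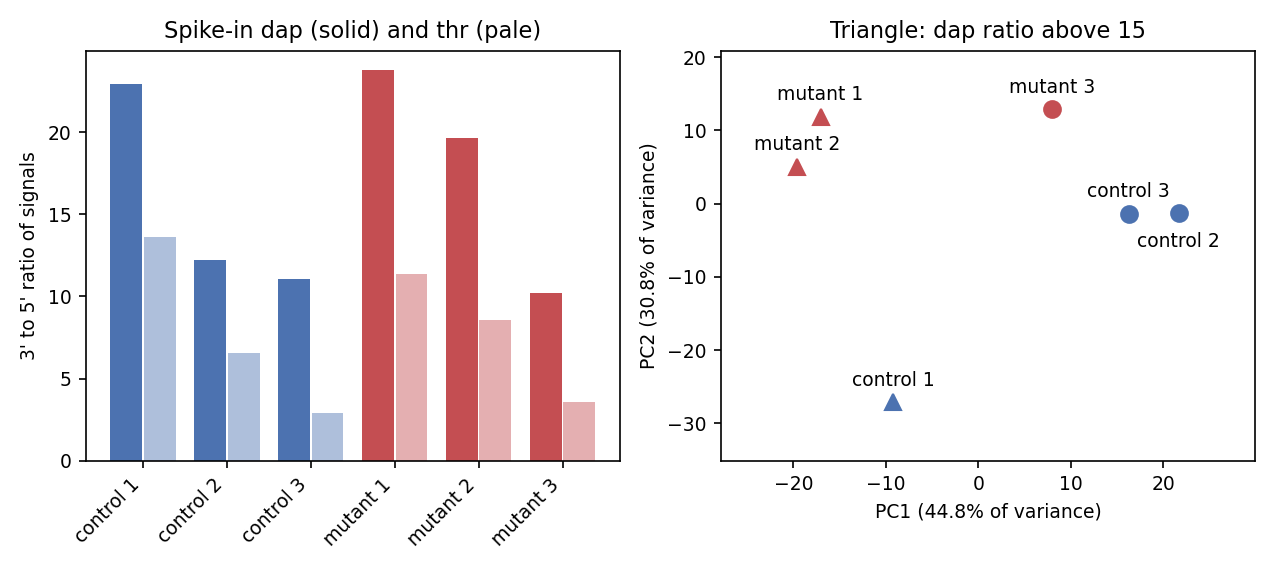
Left, ratio of 3' to 5' signal (no unit) of the spiked transcripts dap (solid) and thr (pale) on each array, blue for control and red for mutant. Right, the 6 arrays on the first 2 principal components of log2 signal (44.8% and 30.8% of variance). Control 1, mutant 1 and mutant 2, with dap ratios of 19.6 to 23.8, lie on the negative side of the first component. The control pools lie on the negative side of the second component and the mutant pools on its positive side.

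The comparison of mutant with control pools addresses which genes of the PSM differ when T-Cre acts on the AC allele, in a series that names the CREB family in its title. No pool carried T-Cre without that allele, so the comparison does not separate the effects of Cre and of AC. In mutant PSM, 9 of 15 tested genes of the list for p53, the transcription factor that responds to DNA damage and other stress, rose. Cdkn1a, a cyclin-dependent kinase inhibitor, rose 5.72-fold (95% confidence interval 4.64 to 7.05, n = 3 pools per genotype). Of 14 tested segmentation genes 2 fell, among them Ripply2, which sets the somite boundary (log2 difference −1.56, SE 0.14), and 1 rose, and of 7 lateral mesoderm markers 3 fell, among them Prrx1 (−1.32, SE 0.14). With the preset correlation, 13 lists were shifted, 4 up, among them the p53 list and markers of epithelia and blood, and 9 down, among them endothelial markers, sterol synthesis and the PSM lists, but with an estimated correlation 1 list passed, that of p53.

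Of 7245 genes, 123 changed, 43 higher and 80 lower in mutant, and 270 had an adjusted p under 0.1. Changes of at least 2-fold were seen in 14 higher and 18 lower genes, and 4 genes rose at least 4-fold. Of 11731 probe sets, 81 changed, 29 higher and 52 lower, of which 8 had no gene name. Unadjusted p lay under 0.05 for 1599 probe sets and for 1089 genes. All 123 genes had 3 mutant values on 1 side of the 3 control values. Over all tested genes, 21.2% did, against 10% by chance. Of the 26 called genes with more than 1 tested probe set, 25 had all of them moving in 1 direction, and Pdha1 (named after its values were seen) did not. Without control 1, 230 genes were called, of which 122 were among the 123, and without mutant 3, 169 were called, of which 101 were. The count was 55 without control 2, of which 54 were among the 123, 48 without control 3, 19 without mutant 1 and 26 without mutant 2, all of them among the 123, and with the spike-in ratio block it was 472, which held all 123.

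Of the 10 genes above the filter with the largest rises, 5 are on the p53 list: Cdkn1a, Ccng1, Trp53inp1, Phlda3 and Perp. After Cdkn1a (log2 difference 2.52, SE 0.14, adjusted p = 9.88e-06) came Ccng1, which encodes cyclin G1 (2.33, SE 0.10, adjusted p = 2.42e-06), and Trp53inp1, a p53-induced nuclear protein (2.30, SE 0.15, adjusted p = 3.65e-05). Mean signal of Ccng1 rose from 1848 ± 98.8 (SD) in control to 9311 ± 732 in mutant. Slc19a2, a thiamine transporter, rose by 2.16 (SE 0.12), and Phlda3, which represses Akt signalling, by 1.90 (SE 0.15). Mt2, a metallothionein, rose by 1.94 (SE 0.31), with 2.75 within the high-ratio arrays and 0.99 within the others. The same values were 1.83 and 0.87 for Perp, 1.91 and 0.46 for Hebp1, and 1.68 and 0.94 for Myl9. Ak1, adenylate kinase 1, rose by 1.37 (SE 0.15). Perp, a desmosome gene, rose by 1.24 (SE 0.24), Hebp1, a heme-binding protein, by 1.18 (SE 0.25), and Myl9, a myosin light chain, by 1.14 (SE 0.23). Calls were lost without mutant 1 or mutant 2 for Mt2, Perp, Hebp1 and Myl9, also without control 2 for Perp and Hebp1, without control 3 for Hebp1 and without mutant 3 for Myl9. Their highest adjusted p with 1 array left out was 0.101 for Mt2, 0.170 for Perp, 0.240 for Hebp1 and 0.173 for Myl9.

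Among genes above the filter, Ripply2 fell most (adjusted p = 0.000622, signal 1070 ± 108 (SD) in control and 363 ± 41.2 in mutant). After it came Rps27, a ribosomal protein gene (−1.34, SE 0.21), Prrx1, a homeobox gene of limb and lateral mesoderm (adjusted p = 0.00178), and Pcdh8, a protocadherin of the forming somite (−1.29, SE 0.28, adjusted p = 0.0485). Dgcr6 fell by 1.25 and Cyp51, lanosterol demethylase, by 1.23 (SE 0.12, adjusted p = 0.00105). Nubpl, an assembly factor of respiratory complex I, fell by 1.19, Dgkk, a diacylglycerol kinase, by 1.14, Oxct1, an enzyme of ketone body use, by 1.11, and Ice2, a subunit of the little elongation complex, by 1.10. Without mutant 1, adjusted p was 0.0833 for Rps27, 0.0701 for Pcdh8, 0.0531 for Nubpl, 0.0701 for Dgkk and 0.0701 for Oxct1. Without mutant 2 it was 0.0639 for Rps27 and for Oxct1 and 0.0897 for Pcdh8, which also lost its call without control 2 (0.121) or control 3 (0.106). The Pcdh8 and Dgcr6 probe sets are of kinds that can cross-hybridise.

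**Figure D2:**
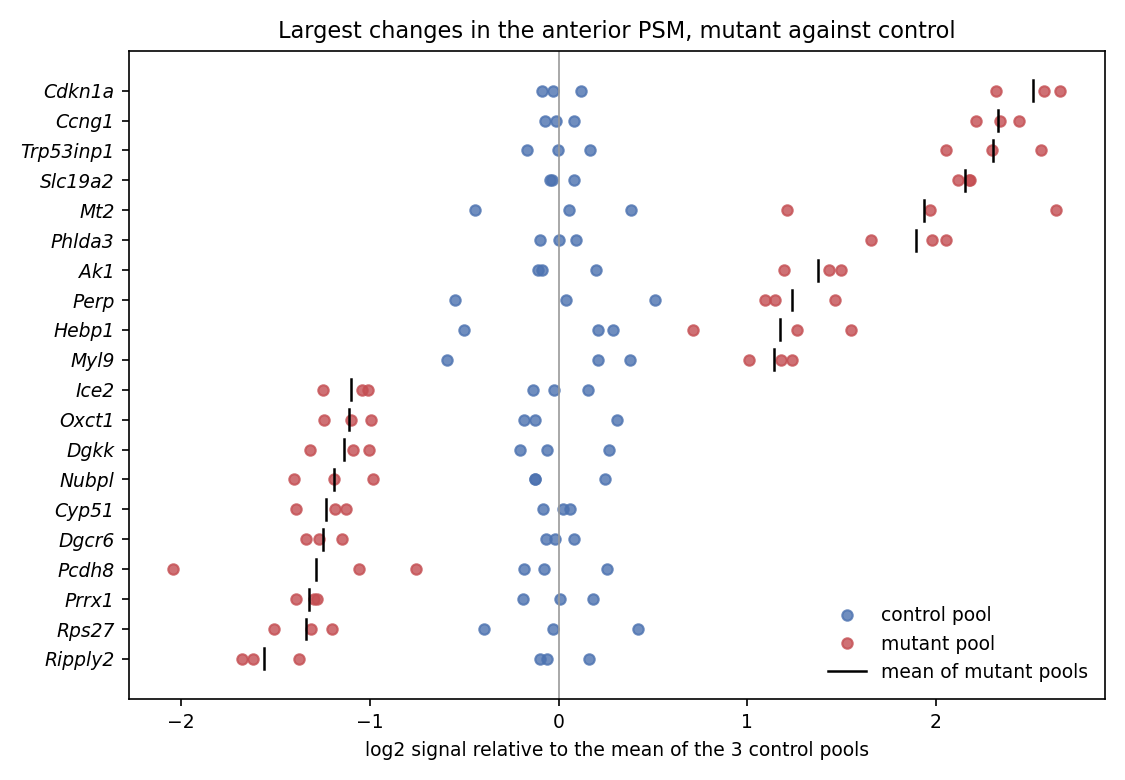
Log2 signal of each pool (points, blue for control and red for mutant, 3 pools per genotype) relative to the mean of the control pools, with the mean of the mutant pools as a black bar, for the 10 genes per direction with the largest called changes. The bars of Cdkn1a (2.52), Ccng1 (2.33) and Trp53inp1 (2.30) lie highest and that of Ripply2 (−1.56) lowest.

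Of 15 tested members of the p53 list, 9 rose, 0 fell and 6 did not pass, while 12 rose when adjusted over the list alone. The p53 list, which shares 2 tested genes with other lists, was shifted up, with a median log2 difference of 0.80 and 13 positive members (camera adjusted p = 1.18e-16, and adjusted p = 0.0195 with an estimated correlation). Besides Ccng1, Cdkn1a, Trp53inp1, Phlda3 and Perp, which the surface ectoderm list also holds, the members that rose were Zmat3 (0.96), Plk2 (0.80) and the cell death genes Pmaip1 (0.99) and Apaf1 (0.59), all 4 named after their values were seen. Aen, an apoptosis nuclease, had 0.49 (adjusted p = 0.0516), Mdm2, the ligase that degrades p53, 0.39 (adjusted p = 0.212), and Btg2 0.64 (adjusted p = 0.242). The list's median was 0.61 within the high-ratio arrays and 0.83 within the others. Surface ectoderm markers, shifted up by a median of 0.60, moved with this list. Without mutant 1, 4 members passed, and without mutant 2, 5 passed. Perp, Pmaip1, Apaf1, Plk2 and Zmat3 lost their calls in 1 or more of the fits without 1 array, all of them without mutant 1 (adjusted p = 0.125, 0.125, 0.181, 0.0976 and 0.0696). Without mutant 2 the values were 0.170 for Perp, 0.170 for Pmaip1, 0.170 for Apaf1 and 0.0578 for Plk2, without mutant 3 they were 0.0548 for Pmaip1 and 0.0583 for Apaf1, without control 3 they were 0.123 for Pmaip1, 0.137 for Apaf1 and 0.0790 for Plk2, and without control 2 they were 0.0618 for Perp and 0.151 for Apaf1.

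Of 14 tested genes of somite segmentation and polarity, 2 fell (Ripply2 and Pcdh8), 1 rose and 11 did not pass. Adjusted over the list alone, 6 fell and 2 rose. The 1 that rose was Pax3, a transcription factor of the dorsal somite and dorsal neural tube (0.94, SE 0.15, adjusted p = 0.0145). Tbx6, a T-box factor of the PSM, had −0.76 (adjusted p = 0.0617), and the Notch ligands Dll1 and Dll3 had −0.72 (adjusted p = 0.0937) and −0.67 (adjusted p = 0.176). The segmentation list had a median of −0.42 (camera adjusted p = 0.0118, and adjusted p = 0.475 with an estimated correlation), with −0.29 within the high-ratio arrays and −0.36 within the others, and 7 of its tested genes are in another list. Endothelial and lateral mesoderm markers moved down with it, by medians of −0.53 and −0.39, and surface ectoderm markers moved up by 0.60. The list's call was lost without mutant 2 (adjusted p = 0.0541). Without mutant 1 or mutant 2, 0 members rose, since adjusted p of Pax3 was 0.0976 and 0.0652. Pcdh8 was not called without control 2 (0.121), control 3 (0.106), mutant 1 (0.0701) or mutant 2 (0.0897), and 4 members fell without control 1 or without mutant 3.

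In the list of posterior PSM and tail bud, 0 of 18 tested genes passed, and 17 had negative values. Limma gave 2 lower genes adjusted over the list alone, Tbx6 and Dll1. The list was shifted down by a median of −0.26 (camera adjusted p = 0.000148, and adjusted p = 0.475 with an estimated correlation), and 12 of its genes are in another list. Within the high-ratio arrays its median was −0.52, and within the others −0.04. Cdx4, a homeobox gene of the tail bud, had −0.44 (adjusted p = 0.172), and Wnt3a −0.51 (adjusted p = 0.234). Blood markers, shifted up, parted in the same way, with medians of 0.78 and 0.01 within the sets. Without mutant 3, 3 members of the posterior list fell and its median was −0.42, without mutant 1 its median was −0.16, and without control 1, 1 member fell.

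Further lists of signalling, patterning and proliferation were shifted down with the preset correlation, those of Wnt, Hox, Notch and the cell cycle, each with an adjusted p of 0.475 with an estimated correlation. Of 29 Wnt pathway genes, 1 fell, over all genes and adjusted over the list alone: Dkk1, a secreted Wnt inhibitor (−0.82, SE 0.16, adjusted p = 0.0357). The Wnt list had a median of −0.14 (camera adjusted p = 0.0120), and Lef1 had −0.46 (adjusted p = 0.114). Of 20 Hox genes, Hoxd1 fell in both counts (−1.07, SE 0.12, adjusted p = 0.00179), the list's median was −0.22 (camera adjusted p = 0.00982), and Hoxb6 had −0.47 (adjusted p = 0.186). Of 16 Notch pathway genes, 0 passed, and 2 were lower adjusted over the list alone, Dll1 and Rbpj, the DNA-binding partner of Notch (−0.37, adjusted p = 0.130), with a list median of −0.16 (camera adjusted p = 0.0212). Of 28 cell cycle genes, 0 passed, adjusted over the list alone as well, with a median of −0.13 (camera adjusted p = 0.0344) and −0.38 for Aurkb (adjusted p = 0.196). Endothelial markers moved down (median −0.53) and surface ectoderm markers up (0.60) beside these lists. Medians within the high-ratio arrays and the others were −0.05 and −0.09 for Wnt, −0.03 and −0.12 for Hox, −0.11 and −0.16 for Notch, and −0.17 and 0.00 for the cell cycle. The Wnt call was lost without control 3 (0.0542) or mutant 2 (0.104) and with the spike-in ratio block (0.0762), the Hox call without control 2 (0.0907) and with that block (0.0760), the Notch call without control 2 (0.0907) or mutant 2 (0.128), and the cell cycle call without control 1 (0.221), mutant 1 (0.101) or mutant 2 (0.0637). Dkk1 was not called without control 2 (0.108), control 3 (0.133), mutant 1 (0.177) or mutant 2 (0.170), 4 Hox genes fell without control 1, 3 Wnt genes fell without mutant 3, and 1 Notch gene fell without control 1 or mutant 3. The Hox median was −0.12 without control 2, −0.11 without mutant 2, −0.35 without mutant 3 and −0.10 with the block, and the Wnt median was −0.09 without control 3, −0.08 without mutant 2, −0.22 without mutant 3 and −0.08 with the block. The cell cycle median was −0.07 without control 1 and −0.08 without mutant 1, and the Notch median −0.10 without mutant 2.

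Of 10 tested surface ectoderm markers, 3 rose, 8 when adjusted over the list alone, and all 10 had positive values. They were Krt19, a simple-epithelium keratin (1.12, SE 0.20, adjusted p = 0.0240), the epithelial adhesion gene Epcam (0.60, SE 0.10, adjusted p = 0.0196) and Perp. Together the surface ectoderm markers had a median of 0.60 (camera adjusted p = 6.64e-10, and adjusted p = 0.132 with an estimated correlation), with 0.73 within the high-ratio arrays and 0.58 within the others. Without Perp, the only tested member on the p53 list, 9 markers had a median of 0.60. Krt8 had 0.44 (adjusted p = 0.0564) and Cdh1, or E-cadherin, 0.63 (adjusted p = 0.0697). Of 13 gut endoderm markers, Epcam rose and Sox17 fell (−1.06, SE 0.19, adjusted p = 0.0250), with 4 higher and 1 lower adjusted over the list alone, and Cldn7 had 0.50 (adjusted p = 0.152). That list's median was 0.50 (camera adjusted p = 0.000148, and adjusted p = 0.221 with an estimated correlation), 0.61 and 0.47 within the sets. Each list shares 4 tested genes with other lists. Of the 4 notochord and floor plate markers, too few for a list test, Krt19 rose, in both counts, and Foxa2 had 0.37 (adjusted p = 0.452). Without control 2, mutant 1 or mutant 2, 0 surface ectoderm markers rose, and without control 3, 1 rose. Adjusted p in these fits was 0.0763, 0.0701, 0.103 and 0.106 (control 3) for Epcam and 0.0506, 0.121, 0.140 and 0.0790 (control 3) for Krt19, and for Perp it was 0.0618, 0.125 and 0.170. Sox17 had 0.0824, 0.0833, 0.0921 and 0.0704 (control 3), and its only tested probe set is of a kind that can cross-hybridise (_x_at).

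Of 8 tested blood markers, Car2, a carbonic anhydrase, rose (0.72, SE 0.15, adjusted p = 0.0428), and adjusted over the list alone 4 rose and 1 fell. The embryonic globin gene Hbb-bh1 had 0.50 (adjusted p = 0.0671), at a signal of 14304 ± 1580 (SD) in control, and Tal1, a regulator of blood and endothelial precursors, −0.74 (adjusted p = 0.141). The list's median was 0.49 (camera adjusted p = 0.0187, and adjusted p = 0.475 with an estimated correlation), with 0.78 within the high-ratio arrays and 0.01 within the others. The list's call was lost without control 1 (0.0809, median 0.29), mutant 1 (0.0749) or mutant 2 (0.0793), and 4 markers rose without mutant 3. Car2 was not called without control 2 (0.123), control 3 (0.0816), mutant 1 (0.195) or mutant 2 (0.188).

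Of 11 tested endothelial markers, 2 fell, 7 when adjusted over the list alone, and all 11 had negative values. They were Kdr, the main VEGF receptor (−0.82, SE 0.14, adjusted p = 0.0154), and Sox17, which is also a gut endoderm marker. The Sox17 probe set is of a kind that can cross-hybridise. Aplnr, the apelin receptor, had −0.72 (adjusted p = 0.0538), and Fli1 −0.77 (adjusted p = 0.0604). The list's median was −0.53 (camera adjusted p = 1.47e-06, and adjusted p = 0.351 with an estimated correlation), with −0.37 within the high-ratio arrays and −0.52 within the others. Of 7 markers of lateral and intermediate mesoderm, 3 fell: Prrx1, Hand2, a factor of heart and limb mesoderm (−0.95, SE 0.15, adjusted p = 0.0130), and Foxf1, a factor of splanchnic mesoderm (−0.87, SE 0.15, adjusted p = 0.0240). Adjusted over the list alone, the same count fell and 1 rose, Bmp4 (0.62, adjusted p = 0.258 over all genes). That list's median was −0.39 (camera adjusted p = 0.00336, and adjusted p = 0.221 with an estimated correlation), with −0.47 and −0.65 within the sets, and its call was lost with no filter (0.0561). Its median was −0.61 without mutant 2 and −0.19 without mutant 3. Each of these lists shares 1 tested gene with another list. Without control 2, control 3, mutant 1 or mutant 2, 0 endothelial markers fell, with adjusted p of 0.0506, 0.0501, 0.0772 and 0.0921 for Kdr and 0.0824, 0.0704, 0.0833 and 0.0921 for Sox17, and 4 fell without control 1. Foxf1 was not called in the same 4 fits (0.0501, 0.108, 0.125 and 0.131), nor Hand2 without mutant 1 (0.0531), where 1 lateral marker fell.

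Of 16 tested genes of sterol synthesis, 4 fell and 12 did not pass, 15 had negative values, and 7 fell when adjusted over the list alone. Besides Cyp51, these were Msmo1, sterol methyl oxidase (−0.62, SE 0.11, adjusted p = 0.0224), Hmgcs1, the synthase ahead of HMG-CoA reductase (−0.55, SE 0.10, adjusted p = 0.0260), and Sc5d, a sterol desaturase (−0.73, SE 0.15, adjusted p = 0.0448). The list's median was −0.23 (camera adjusted p = 6.56e-06, and adjusted p = 0.221 with an estimated correlation), with −0.14 within the high-ratio arrays and −0.36 within the others, and no member is in another list. Surface ectoderm markers moved up and endothelial markers down beside it. Without control 2, control 3, mutant 1 or mutant 2, Cyp51 alone passed. In these fits adjusted p was 0.0683, 0.123, 0.121 and 0.0905 for Msmo1, 0.105, 0.109, 0.0701 and 0.134 for Hmgcs1, and 0.123, 0.127, 0.181 and 0.163 for Sc5d.

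**Figure D3:**
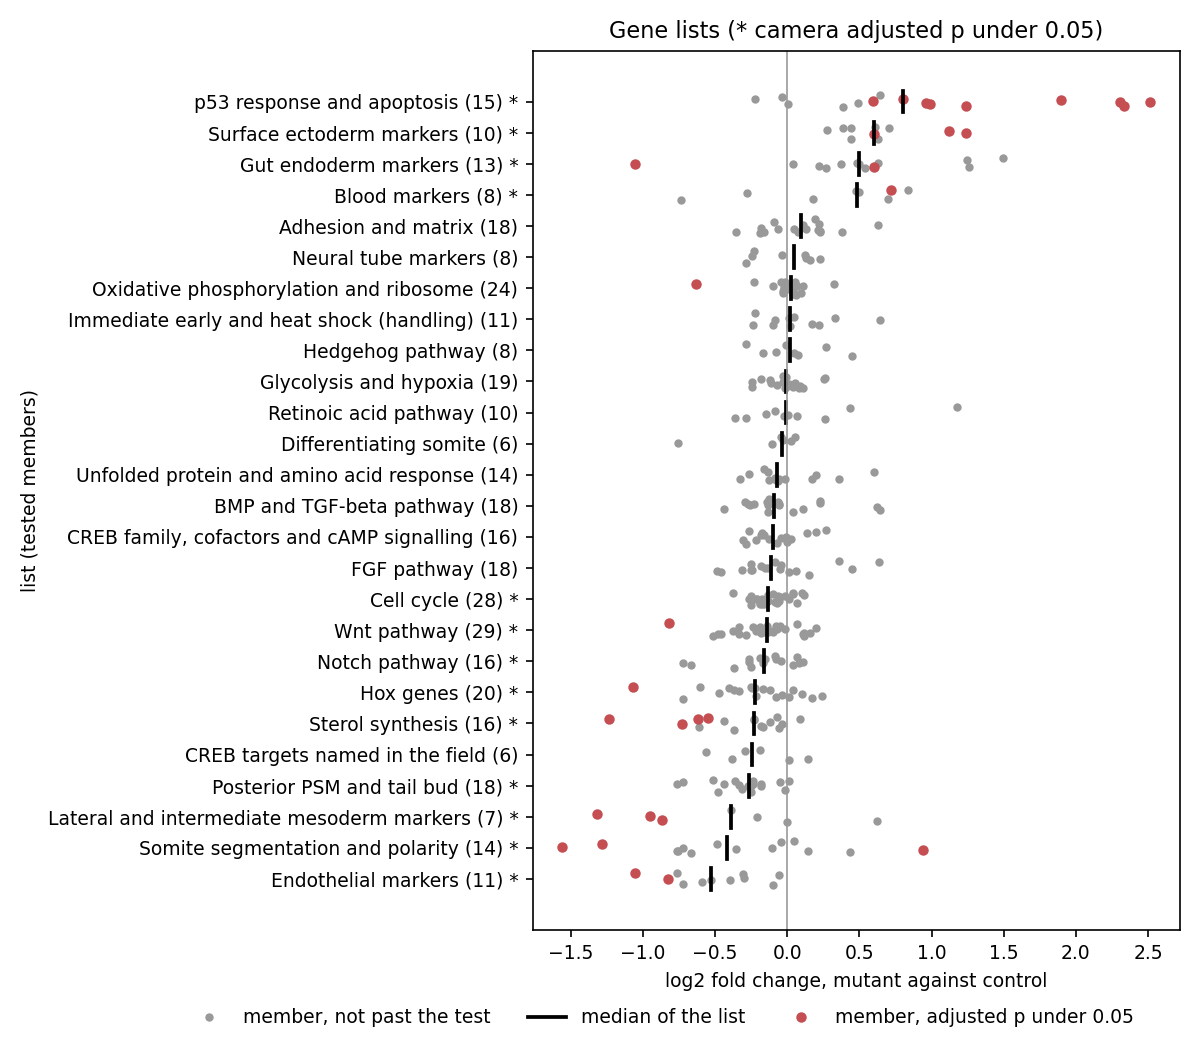
Log2 difference, mutant minus control, of each tested member (points, red where adjusted p is under 0.05) and the median (bar) of the 26 tested lists, with the number of tested members in brackets. Medians run from 0.80 for the p53 list to −0.53 for the endothelial list.

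The lists for the CREB family did not pass the list test over all arrays. Of 6 tested CREB targets, 0 passed and 1 was lower adjusted over the list alone, Rgs2, a regulator of G protein signalling (−0.56, adjusted p = 0.126 over all genes), and the list's median was −0.24 (camera adjusted p = 0.102). Adjusted p of this list was 0.0273 without control 1 (median −0.30), 0.273 with the spike-in ratio block and 0.858 with no filter, over 18 members. Of the 12 CREB targets below the filter, Egr1 alone passed with no filter, and it was higher in mutant (2.49, adjusted p = 8.02e-05), with mean signals of 65.5 in control, near background, and 370 in mutant. Of 16 tested genes of the CREB family, its cofactors and cAMP signalling, 0 passed, adjusted over the list alone as well (median −0.10, camera adjusted p = 0.365), and its median was −0.22 without control 1, −0.04 without control 2 and −0.18 without mutant 3. Creb1 had 0.14 (SE 0.11, adjusted p = 0.605). Crem lay below the filter and had 0.27 (adjusted p = 0.613 with no filter) in the probe set used, with mean signals of 94.6 in control and 113 in mutant. Its other probe sets moved down, from 97.0 to 82.6 and from 62.3 to 50.1. All these signals are dim, so the direction of Crem is not settled. Gt(ROSA)26Sor, the transcript of the locus that holds the allele, also lay below the filter, which acts on the mean of log2 signals. With no filter its log2 difference was −2.92 (SE 0.32, adjusted p = 0.00125). Its signal was 824, 356 and 865 in the control pools and 98.1, 62.9 and 91.7 in the mutant pools. These mutant signals lie near the 5th percentile of the probe sets in the table on their arrays (72.5, 70.4 and 66.5). The size of the difference therefore depends on background, and it was −2.72 with an offset of 16 and −2.25 with an offset of 64.

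The other 11 tested lists did not pass over all arrays. Camera adjusted p was 0.705 for the FGF pathway (median −0.11), 0.741 for the retinoic acid (−0.01), Hedgehog (0.02) and BMP and TGF-beta pathways (−0.09) and for differentiating somite (−0.04), 0.969 for glycolysis and hypoxia (−0.01) and for the unfolded protein and amino acid response (−0.07), and 0.281 for adhesion and matrix (0.09). It was 0.741 for oxidative phosphorylation and ribosome (0.02), 0.741 for the immediate early and heat shock genes (0.02) and 0.910 for neural tube markers (0.04), a list that passed with no filter (0.0422). The adhesion and matrix list passed without mutant 2 (0.0317). With 1 array left out, the medians of these 11 lists lay between −0.20 (differentiating somite, without control 1) and 0.16 (Hedgehog, without mutant 2). Members of these lists that did not pass included Rbp4, a retinol-binding protein (1.18, SE 0.48, adjusted p = 0.274), Etv5, an FGF target (−0.48, adjusted p = 0.124), Cdon (0.45, adjusted p = 0.128), Aldh1a2, the retinoic acid synthase of the PSM (0.44, adjusted p = 0.214), Bmp2 (0.64, adjusted p = 0.155), Ddit4 (0.60, adjusted p = 0.178) and Foxc2 (−0.75, adjusted p = 0.274). The log2 fold change of Rbp4 was 0.51 without mutant 1. Ndufb2, a subunit of respiratory complex I, was the 1 gene of these lists that passed (−0.63, SE 0.14, adjusted p = 0.0496). Adjusted over the list alone, Cdon and Cdh1 were higher and Ndufb2 lower. Ndufb2 was not called without control 2 (0.0506), control 3 (0.153), mutant 1 (0.207), mutant 2 (0.0921) or mutant 3 (0.0907). Of the sex-linked genes, Xist alone was tested, and it had 0.11 (SE 0.28, adjusted p = 0.899). Within the high-ratio arrays it had 1.04 and within the others −0.72. With 1 array left out it ran from −0.22 (without control 1) to 0.36 (without mutant 3). Of its 3 tested probe sets, 2 moved up and 1 down, so the value does not show that the pools were balanced in sex.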

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

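The genes below were singled out after their values were seen, and they lay below the signal filter, outside the comparisons of the report. With no filter, 38 such genes passed in limma, 26 higher and 12 lower in mutant, and 3007 did not. The 26 stood above their level in the control pools. Eda2r, a p53 target that encodes a receptor of the tumour necrosis factor family, was higher by 2.55 on the log2 scale (SE 0.16, adjusted p = 1.51e-05), with mean signals of 139 in control and 823 in mutant. Ddit4l, a regulator of mTOR signalling, was higher by 3.06 (SE 0.20, adjusted p = 1.64e-05), with signals of 64.6 and 554. Egr1, an immediate early gene on the lists of CREB targets, FGF pathway and handling, was higher by 2.49 (SE 0.19, adjusted p = 8.02e-05), with signals of 65.5 and 370. All 3 had their 3 mutant values above their 3 control values. Control means of 64.6 and 65.5 lie near an array's 5th percentile over the probe sets in the table (59.6 to 72.5). The size of these fold changes therefore depends on background, and the log2 difference of Egr1 (below the filter) was 2.25 with an offset of 16 and 1.75 with an offset of 64.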

How the results depend on the processing

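The spike-in ratio block was chosen after seeing the data, and the other alternatives before. No called result changed direction under any of them. Of 2111 alternative values for 115 single-gene results, 1886 stayed on their side of the threshold, 111 lost the call, 92 gained one and 22 were values without a call that changed sign or, for Egr1 and Gt(ROSA)26Sor below the filter, moved with the offset by more than the spread. Of 542 for the 26 lists, 461 stayed, 46 lost the call, 3 gained one and 32, without a call, changed direction. Among the 34 named genes that changed, Ccng1 and Slc19a2 kept the call under every alternative run, and 10 more lost it in the equal-variance test alone. Probe sets with a mean log2 signal below that of a signal of 349 were not tested, and background limits what a fold change of dim probe sets can show.

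The counts of changed probe sets (81), higher (29), lower (52) and of changed genes (123) became 48, 14, 34 and 74 with the filter at the 60th percentile, 1196, 526, 670 and 943 with array quality weights, 243, 88, 155 and 270 at adjusted p under 0.1, 4, 3, 1 and 2 in the equal-variance test, and 555, 242, 313 and 472 with the spike-in ratio block. With no filter, 47 probe sets were higher. Leaving out each array in turn gave 24 to 149 changed probe sets, 11 to 58 higher, 13 to 91 lower and 19 to 230 changed genes. Of the 13 shifted lists, 1 passed with an estimated correlation and 3 with fry. Those that passed with fry were p53 (adjusted p = 3.98e-05), lateral and intermediate mesoderm (0.0119) and surface ectoderm (0.0228). A looser threshold passes more by construction and the equal-variance test does not share variance between genes. The cause was not tested for the filter, the weights, the spike-in ratio block and the single arrays. Array weights ran from 0.32 for control 1 to 4.29 for control 3.

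With replicate number as a block, although the numbers do not pair the arrays, 120 probe sets changed, 51 higher and 69 lower, with 176 genes, of which 115 were among the 123, and 13 lists.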

Other observations

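All tests of explanations in this part were chosen after the results were seen, except the test of opposed probe sets, whose bounds were written before its share was computed, when opposed probe sets of Xist had already been seen. The genes named next were chosen after their values were seen. Of 5 surface ectoderm markers below the signal filter, 2 were higher in mutant with no filter, Trp63, the p53 relative that marks stratifying epithelium, by 1.04 (adjusted p = 0.0467) and Tfap2c by 0.81 (adjusted p = 0.0373). The other 3, Dlx5, Grhl2 and Grhl3, had 0.02, 0.55 and 0.29 and did not pass. Among dim genes on no list, Krt5, a basal keratin, was higher by 0.95 (adjusted p = 0.0446). Actc1, cardiac actin, was higher by 1.70 (adjusted p = 0.0191), and Polk, a DNA polymerase that copies past lesions, by 0.93 (adjusted p = 0.0347). Kif7, a regulator of Hedgehog signalling, was lower by 1.49 (log2 difference −1.49, adjusted p = 0.00421), and Prodh, which neighbours Dgcr6, by 1.06 (−1.06, adjusted p = 0.0135). The 8 called probe sets with no gene name included the largest rises among all tested probe sets, 3.27 and 3.07, and their largest falls were −1.82 and −1.33.

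In the gene order of GRCm38.p6, 5 pairs of called genes were direct neighbours among the tested genes, against a mean of 2.01 in 2000 random draws, with a permutation p of 0.0515 (one-sided). The pairs were Guk1 with Mrpl55, Car3 with Car2, Plac8 with Coq2, Smarcad1 with Ndnf, and Zdhhc3 with Exosc7, of which Plac8 (0.86) and Coq2 (−0.94) moved in opposite directions. With no filter there were 8 pairs against a mean of 2.67 (permutation p = 0.00750), and with the spike-in ratio block 49 against 30.5 (permutation p = 0.00100). These 3 checks were not adjusted for each other, and no explanation was tested.

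The p53 list was higher in mutant, by a median of 0.80. Its lower median within the sets of arrays was 0.61, though each set compares 1 pool with 2. With the spike-in ratio block, 10 of its 15 tested members were called higher and 0 lower. These values argue against the structure that the dap ratio follows as the whole cause. The list also kept its camera call with that block (adjusted p = 9.45e-18). That call used the preset correlation, at which each other split of the arrays called lists too, so it is not counted here. Cre recombinase or its transgene may act on p53 targets without the AC allele, and since 0 arrays held T-Cre without that allele, the effects of Cre and of AC cannot be told apart and both stay open. Lower activity of the CREB family also stays open, since the 6 tested CREB targets gave an adjusted p of 0.102 (0.0273 without control 1, 0.273 with the block and 0.858 over 18 members with no filter), with members on both sides of 0, and the 1 target that passed with no filter, Egr1, was higher (2.49), from a control signal near background.

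The lists of segmentation, posterior PSM, endothelial and lateral mesoderm genes were shifted down in mutant with the preset correlation, but not with an estimated one (adjusted p = 0.475, 0.475, 0.351 and 0.221). A lower share of PSM in the mutant pools would raise the markers of other cell types alike only if these entered in fixed proportions. The median of the surface ectoderm list exceeded that of the endothelial list by 1.14. The middle 50% of the first lay above 0 and that of the second below. This argues against an even rise of all other cell types, but not against a lower share of PSM. Gut endoderm (median 0.50) and blood markers (0.49) were also up, and a lower share with uneven proportions stays open. For segmentation, endothelial and lateral mesoderm markers, the medians were negative within both sets of arrays, and the median nearest to 0 was −0.29. The shift was thus not confined to 1 set, though each set compares 1 pool with 2. All 3 lists kept their calls with the block. At the preset correlation, however, each of the other splits of the arrays called lists too, from 4 to 13. Each of those splits sets 2 pools of 1 genotype against 1 and so keeps part of any genotype difference. Their counts are thus not a rate of false calls, and how many calls are false is unknown, so these calls cannot decide. The dap ratio's structure is therefore not excluded for these lists. For posterior PSM genes it cannot be told apart from the genotype, with a median of −0.0416 within the low-ratio arrays and a call kept with the block (adjusted p = 0.00216). More surface ectoderm in the mutant pools, and less lateral and endothelial mesoderm in the tissue or in the piece dissected, stay open as untested.

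Probe sets also parted the arrays by the dap ratio: 748 passed for this split, 271 higher and 477 lower in the high-ratio arrays, with 310 genes, of which 0 were among the 123. This 0 does not show that the sets of genes are separate. All 123 had genotypes that did not overlap, and such a gene cannot also part the arrays fully by the dap ratio. Whether labelling that stopped at different distances from the 3' end contributes could not be decided. Among 630 genes that held a called probe set for this split, 217 of 695 other probe sets (31.2%) moved against the called one. No share expected without such labelling was computed, and no distance from the 3' end was used. For mutant against control 0 of only 27 did, among 67 genes that held a called probe set. These are not the 123 genes called at the gene level, and Pdha1 is not among them. The share of all genes with several probe sets that had both signs differed less, 47.4% for this split and 41.0% for mutant against control. Whether pools that differ in cell types contribute could not be decided either. Of 7 lists of other cell types, 1, the neural tube markers, was shifted (camera adjusted p = 0.0442), close to the threshold. The lists of Hox genes (adjusted p = 0.000305), posterior PSM (0.00338) and Wnt pathway (0.00674) were also shifted. At the preset correlation, however, splits of the arrays with 0 called probe sets called from 4 to 13 lists, against 4 here. Those splits also keep part of any genotype difference, so how many calls are false is unknown, and these calls cannot decide. No biological explanation other than cell types was tested.

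The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At least as many probe sets as in the real one were called in 2 of the 10 splits, the real one with 81 and the split by the dap ratio with 748, the highest of the others, which points to a structure of the arrays. The same split gave 477 as its larger count in 1 direction, against 29 higher and 52 lower for the real one, and 310 genes against 123. At the preset correlation each of the other splits called lists, from 4 to 13 of them, against 13 in the real one, and the highest was that of control 1, mutant 2 and mutant 3 against the rest. Each of these other splits sets 2 pools of 1 genotype against 1 and so keeps part of any genotype difference. Their counts are thus not a rate of false calls. With the split by the dap ratio in the model, mutant against control gave 555 probe sets and 472 genes.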
